A study of Homo sapiens with 12 samples.

How the data were processed

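RNA of the HT-29 clones 5M21 and 5F7 was compared with RNA of clone 5F31 on 12 Agilent 2-colour arrays, 8 of them human and 4 mouse, with 2 arrays per comparison in opposite dye orientations. Per the file headers, the deposited scanner files hold raw median signal intensities of each spot and of its local background in both channels, without normalization, and processed intensities that Feature Extraction background-subtracted, detrended and dye-normalized. They also hold the log10 ratio of the red over the green processed signal, as deposited by the authors. The deposited value tables of the series hold the same log10 ratios, with the sign turned on the arrays where 5F31 was labelled Cy5, so that they run as clone over 5F31 as labelled; on every array 100% of the values equalled the scanner file's within a tolerance of 1e-04, and the median was 0 except for xenograft 5F7 replicate 2 (-0.0327). The number of columns of those tables without a sample was 0. The headers give Feature Extraction 10.1.1.1 for the arrays titled as culture, 8.1.1.1 for the human arrays titled as xenograft and 10.5.1.1 for the mouse arrays, whereas the labels list 8.5.1.1 for all; the labels also give human as the organism of the mouse arrays.

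Analysis used R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). Median signals were used because mean signals are missing from some files, although mean signals had been planned. Background was corrected with normexp (offset 50) and each array was normalized by loess. Spots marked as outliers on any array of an experiment were left out, and probes were kept where at least 1 of the 3 clones was well above background, by the file's own marks, on all of its arrays in the experiment, which left 24927 probes for the arrays titled as culture, 23402 for the human arrays titled as xenograft and 19319 for the mouse arrays. Of 41000 probes shared by the human designs, 24127 were named by accession, 1929 by symbol and 940 by synonym from the RefSeq annotation given; 14004 stayed unnamed, and 9 had accessions of different genes. A gene was represented by its brightest probe. The mouse probes carry no gene names in the files and no table paired them with genes, so they were tested by probe, and mouse lists of 612 genes could not be used.

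Each experiment was fitted with lmFit and eBayes over its 4 arrays, with 1 signed coefficient per clone and no dye coefficient, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The sign of each array follows the dyes in the labels, which the signals go against (see the report); the labels' directions were kept because the design was fixed on them, and are not settled. The prior degrees of freedom were 2.17, 2.90 and 2.81 for the arrays titled as culture, the human arrays titled as xenograft and the mouse arrays. The number of arrays limits the precision. Contrasts of 5M21 with 5F7 came from the same fits, and the difference of clone effects between the human sets from 1 fit over 8 arrays and 12337 genes. The overlap expected of independent lists is the product of their sizes over the genes tested, and the correlation expected of unrelated clones with a shared reference came from 20 seeded simulations. Gene lists (19 human lists of 761 genes, 760 of them in the RefSeq table) were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and also with an estimated correlation and with fry. Folds against a clone whose probe was not well above background are lower bounds, computed from single-channel intensities after loess and quantile normalization of average intensity.

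Designs, gene lists, alternatives and the choice of genes named were fixed before the data were examined, except where the text says that they were chosen later. For each comparison with 5F31 the rule names the 8 largest rises and 8 largest falls past the threshold that had the same sign on both arrays, were well above background in the brighter clone and had a proper symbol. It adds up to 4 members past the threshold per list, or up to 2 where fewer than 2 pass, the 6 largest mean changes in each direction of genes shared by both clones, the 4 largest in each direction of the difference between the human sets, and always TYMS; for the mouse arrays it names 2 probes in each direction. Not all genes so chosen are printed, and some genes and 1 of the 19 lists are not reported here. Alternatives were no background subtraction, the deposited log ratios, median centring, scaling between arrays, other filters on dim probes, a dye coefficient per gene, the mean over a gene's probes, a 2-fold minimum and leaving out each array. Slide as a random block was not run, because all 4 arrays titled as culture, and all 4 mouse arrays, share 1 slide and each human array titled as xenograft has its own.

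The fit was tested on simulated data with known changes. On the arrays titled as culture it recovered 76.1% of 2-fold changes for 5M21 and 86.6% for 5F7, and on the human arrays titled as xenograft 98.5% for both, with at most 0.244% unchanged genes among the calls of any experiment. With a dye coefficient that share rose to at most 5.48%. A simulated raised list passed camera with the preset correlation (adjusted p = 2.43e-08, 1.63e-11 and 3.73e-20 in the 3 experiments) and did not pass with an estimated correlation (adjusted p = 0.991, 0.304 and 0.174), while 0 of 18 random lists passed camera in each. The simulated genes varied independently and the random lists held unchanged genes only, so false calls among lists of correlated genes were not tested.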

Results

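HT-29 is an established human colorectal adenocarcinoma cell line. The series compared 3 of its clones, all derived from drug-resistant populations: 5M21 from cells selected with methotrexate, and 5F7 and 5F31 from cells selected with 5-fluorouracil. According to the submitters, 5M21 and 5F7 invade collagen in vitro and form lung metastases as xenografts in immunodeficient mice, whereas 5F31 does neither. The comparisons therefore ask which transcripts set each of the first pair of clones apart from 5F31, in cell culture and in xenograft tumours, and on mouse arrays which host transcripts differ between the tumours. Each of the 12 2-colour Agilent arrays carried 1 clone against 5F31. There were 4 arrays titled as culture, 4 human arrays titled as xenograft and 4 mouse arrays of the xenografts, and within each set 5M21 and 5F7 had 2 arrays each, in opposite dye orientations.

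The human arrays carry a conflict that bears on every culture and xenograft label. The series text assigns single 44K arrays to the cells and 4x44K arrays to the xenografts, while the file headers give the design with 4 arrays on 1 slide for the arrays titled as culture and a design with 1 array per slide for those titled as xenograft. They are therefore called arrays titled as culture and arrays titled as xenograft throughout. Red spots well above background made up 61.4% to 66.0% of the probes on the arrays titled as culture, 63.4% to 91.6% on the human arrays titled as xenograft and 46.6% to 53.1% on the mouse arrays. The 91.6% came from xenograft 5F7 replicate 2, which also held 4706 spots marked as outliers, against 40 to 187 on the other human arrays titled as xenograft. Swapped arrays of 1 comparison correlated across genes with r = 0.839 for 5M21 and 0.829 for 5F7 (culture), 0.884 and 0.859 (xenograft, human) and 0.763 and 0.729 (mouse probes). Genes are not independent replicates, so these values describe the arrays only. The labels do not say whether the arrays of a swapped pair used separate RNA extracts, so the p-values measure the spread between arrays, which may be technical. Their small number limits the precision. Ratios are given as the channel labelled 5M21 or 5F7 over the channel labelled 5F31, with the standard error of the limma fit and n = 2 arrays per comparison.

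The direction of these ratios rests on the channel labels, and the signals go against them. Per the labels 5F31 is the RNA on every array, so its channels should agree best between the 5M21 and the 5F7 arrays. Between those arrays the channels labelled 5M21 and 5F7 correlated across probes with r = 0.989 to 0.998 (culture), 0.992 to 0.998 (xenograft, human) and 0.992 to 0.997 (mouse), whereas the channels labelled 5F31 correlated with r = 0.961 to 0.974, 0.974 to 0.981 and 0.976 to 0.978. The SD across probes of the difference between the 5M21 and 5F7 arrays was 0.157, 0.117 and 0.112 for the channel labelled as the clone and 0.529, 0.412 and 0.364 for the channel labelled 5F31. The channels that agreed best were those labelled 5M21 and 5F7 in all 3 experiments. If the labels of the channels are exchanged on every array, every log2 ratio below changes sign and higher and lower trade places, while sizes and limma p-values for the same genes stay. Directions below are as labelled and are not settled, and a clone's name stands for the channel so labelled.

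On the arrays titled as culture, the channel labelled 5M21 differed from that labelled 5F31 in interferon-response genes and a block of neighbouring genes around TYMS, which were higher as labelled, and in goblet cell and cholesterol synthesis genes, which were lower. INPP5D, a lipid phosphatase known from blood cells, rose in the channel labelled 5M21 by a log2 ratio of 5.53 ± 0.36, and PLAC8 by 5.21 ± 0.28. The secreted ligand WNT11 was 20.9-fold higher and the calcium-binding protein S100A2 20.6-fold. In the other direction, CXCR4, the receptor of the chemokine CXCL12, was 103-fold lower (-6.68 ± 0.36), and AUTS2 was lower too, well above background in the channel labelled 5M21 on 1 of 2 arrays. SYT13 was 69.6-fold lower, the growth factor receptor adaptor GRB10 68.0-fold, the TGF-beta pseudoreceptor BAMBI 58.0-fold and the endodermal transcription factor FOXA2 44.3-fold. The actin-binding protein CALD1 was at least 66.0-fold lower, because its probe was not well above background in 5M21. These genes had limma adjusted p between 0.00422 and 0.00771.

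Of 42 interferon-response genes tested in this comparison, 33 rose and 1 fell as labelled, and 38 rose and 1 fell when adjusted over the list alone (limma camera adjusted p = 8.91e-13). None of the list calls named here for 5M21 on the arrays titled as culture passed camera with the correlation estimated per list (adjusted p = 0.341 to 0.477 with an estimated correlation). The simulated raised list did not pass with an estimated correlation in any experiment either. In the fits of 4 arrays, here and below, failing with an estimated correlation therefore cannot show that a list did not move. The simulated genes varied independently, however. On these arrays the estimated correlation of the lists named here lay between -0.0134 (integrins, laminins and matrix receptors) and 0.388 (interferon-response genes), against the preset 0.01. The simulation does not bear on lists whose members move together, and their p-values at the preset correlation may be too small. IFIT2 was 23.4-fold higher, BST2 rose by a log2 ratio of 3.81 ± 0.30 and IFI6 by 3.70 ± 0.30. Among 18 antigen presentation genes 12 rose and none fell, with the same numbers adjusted over the list alone (camera adjusted p = 2.91e-05), led by the immunoproteasome subunits PSMB9 (log2 ratio 2.45 ± 0.25) and PSMB8 (2.02 ± 0.33) and the peptide transporter TAP1 (1.96 ± 0.27). Goblet cell and mucin genes moved the other way: 12 of 22 fell and 3 rose, and 13 fell and 4 rose adjusted over the list alone (camera adjusted p = 0.00582). AGR3 fell by 4.57 ± 0.44, the gel-forming mucin MUC5AC by 3.21 ± 0.37 and the secretory-lineage gene REG4 by 2.70 ± 0.10 on the log2 scale. Of 28 cholesterol and fatty acid synthesis genes 17 fell and 1 rose (20 and 1 adjusted over the list alone, camera adjusted p = 5.76e-05), among them HMGCS1, an enzyme early in cholesterol synthesis (-2.07 ± 0.10), and SQLE (-1.64 ± 0.11). Among 16 enterocyte genes 8 fell and 1 rose (camera adjusted p = 0.0242, same numbers adjusted over the list alone), including the microvillus protein VIL1 (-2.34 ± 0.10). Integrins, laminins and matrix receptors had 14 of 37 members lower and 1 higher, as when adjusted over the list alone (camera adjusted p = 0.0357). The member that rose was YES1, a kinase encoded next to TYMS. The mesenchymal list had 6 of 15 members higher and none lower (camera adjusted p = 0.0242), with the receptor kinase AXL (log2 ratio 4.27 ± 0.14) and the matrix protein TGFBI (3.40 ± 0.11) higher; its median log2 ratio of 0.19 turned to -0.000935 with no filter on dim probes. In all, 4381 of 11428 genes passed the threshold, 2008 higher and 2373 lower in the channel labelled 5M21, and 1425 also differed at least 2-fold. Leaving out 5M21 replicate 1 or replicate 2 left 353 or 329 genes, centring on the median in place of loess 263, and scaling between arrays on all spots 0 (5726 at unadjusted p below 0.05 in the fit as reported).

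On the arrays titled as culture, the channel labelled 5F7 differed from that labelled 5F31 in many genes that also led the list for 5M21. As labelled, INPP5D was 35.9-fold higher in 5F7 and PLAC8 30.6-fold. NNMT, which methylates nicotinamide, was 17.0-fold higher. NEUROG3, the transcription factor that specifies enteroendocrine cells, was 16.4-fold higher (log2 ratio 4.04 ± 0.20) and the insulin-like growth factor IGF2 5.75-fold (2.52 ± 0.11). CALD1 was at least 32.2-fold lower and AUTS2 was lower, both not well above background in 5F7, while SYT13 was 49.0-fold, CXCR4 43.7-fold, GRB10 33.8-fold and FOXA2 22.4-fold lower. The limma adjusted p of these genes lay between 0.00367 and 0.0104. Interferon-response genes rose in 30 of 42 cases and fell in 1 (32 and 2 adjusted over the list alone, camera adjusted p = 2.87e-09), with IFI44 14.7-fold and BST2 13.3-fold higher. For the lists named here for 5F7 the adjusted p was 0.473 to 0.557 with an estimated correlation. Antigen presentation genes rose in 10 of 18 cases with none lower, also adjusted over the list alone (camera adjusted p = 3.12e-05), and the MHC light chain B2M rose by 2.16 ± 0.10. Goblet cell and mucin genes fell in 14 of 22 cases and rose in 4, with the same numbers adjusted over the list alone (camera adjusted p = 0.00982), REG4 by 3.20 ± 0.10 and the mucus protein FCGBP by 2.37 ± 0.11. Cholesterol and fatty acid synthesis genes fell in 15 of 28 cases and rose in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 8.24e-05); HMGCS1 fell by 2.31 ± 0.10. Of 20 Wnt target and intestinal stem cell genes 11 fell and 4 rose (12 and 4 adjusted over the list alone, camera adjusted p = 0.0440), among them the receptor EPHB3 (-2.42 ± 0.20) and the stem cell transcription factor ASCL2 (-2.11 ± 0.12). In 5M21 10 of them fell and 4 rose, which did not pass (camera adjusted p = 0.0527). As in 5M21, enterocyte genes fell in 8 of 16 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0201). Integrins, laminins and matrix receptors fell in 13 of 37 cases and rose in 1 (13 and 2 adjusted over the list alone, camera adjusted p = 0.0267). The mesenchymal list had 6 of 15 members higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.0490), with AXL higher by 3.46 ± 0.14. In all, 4351 genes passed, 2157 higher and 2194 lower as labelled, 1492 of them by at least 2-fold. Without 5F7 replicate 1 the count was 1367; median centring gave 312 and scaling between arrays on all spots 0 (5809 at unadjusted p below 0.05 in the fit as reported).

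Both clones moved in the same direction in 2661 genes on the arrays titled as culture (1249 higher, 1412 lower), where independent lists would share 379 and 456, and 68 genes passed in opposite directions. The count of 2661 was 309 or 272 without 5M21 replicate 1 or replicate 2, 149 with median centring in place of loess and 0 with scaling between arrays on all spots. The log2 ratios of the clones correlated across genes with r = 0.774 and a covariance of 0.485. Simulated unrelated clones against 1 shared reference gave r = 0.472 and a covariance of 0.313, and unchanged clones r = 0.00132. The simulated errors were drawn independently, so here and below the value for unchanged clones lies near 0 by construction. Because 1 RNA was on every array, part of the excess may come from the shared reference. The direct contrast of 5M21 with 5F7 passed in 2 genes, named after their values were seen: PHLDB2 (log2 difference 3.91 ± 0.13) and SPP1, the secreted matrix protein osteopontin, both with a higher ratio over 5F31, as labelled, on the 5M21 arrays (limma adjusted p = 0.0284). SPP1 was not well above background in the channel labelled 5F31 of the 5M21 arrays. The log2 signal of PHLDB2 was 9.67 and 9.70 in the channels labelled 5M21 and 5F7, and 7.22 and 11.16 in the channels labelled 5F31 on the same arrays. For SPP1 the channels labelled 5M21 and 5F7 had 10.25 and 10.22 and that labelled 5F31 had 11.20 on the 5F7 arrays, so both differences lay in the channels labelled 5F31. This count moved with the processing, to 591 without background subtraction, 346 from the deposited log ratios, 2433 with a dye coefficient per gene and 0 without any 1 of the 4 arrays, with 2715 genes at unadjusted p below 0.05.

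**Figure D1:**
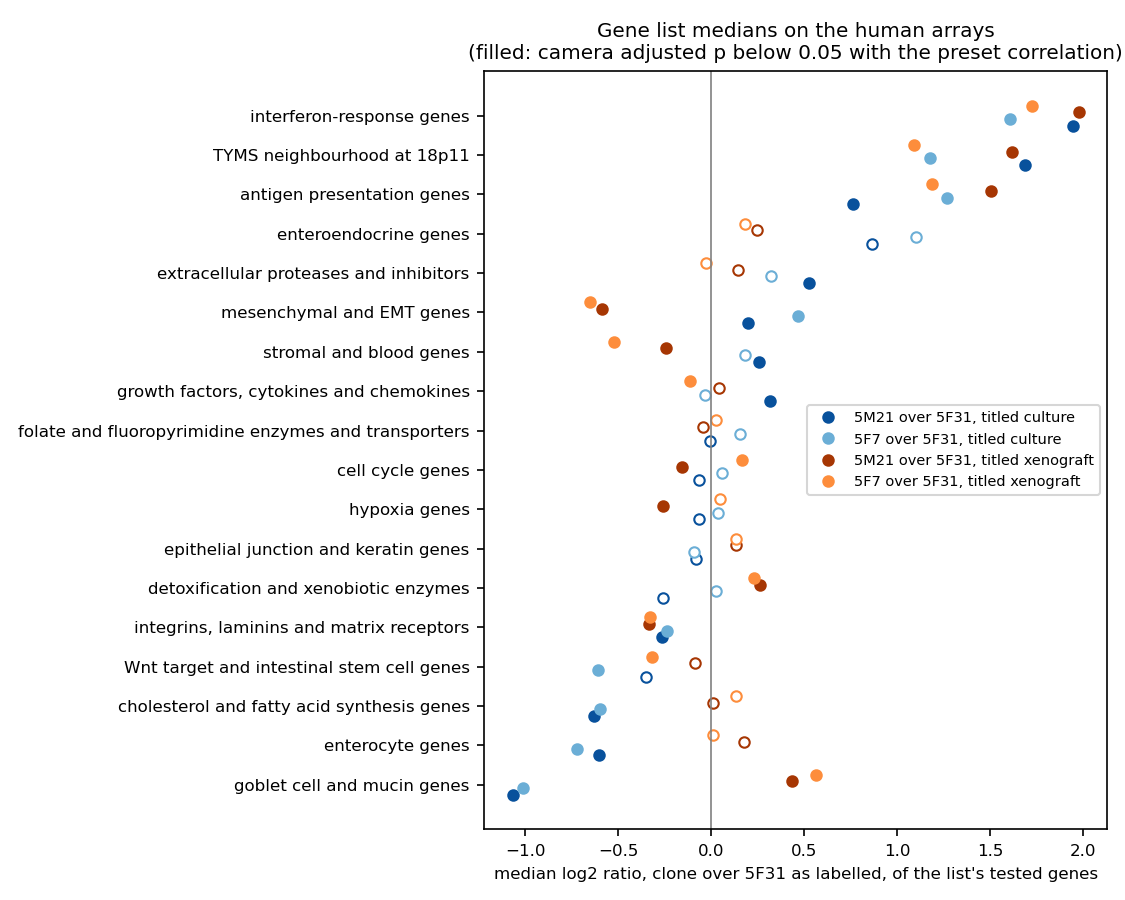
Median log2 ratio (horizontal axis, clone over 5F31 as labelled) of the tested genes of each of 18 gene lists (vertical axis) in the 4 comparisons on the human arrays; filled points passed camera with the preset correlation and open points did not. Interferon-response genes lay between 1.61 and 1.97 in every comparison, while goblet cell and mucin genes lay at -1.07 and -1.01 on the arrays titled as culture and at 0.43 and 0.56 on those titled as xenograft.

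On the human arrays titled as xenograft, the channel labelled 5M21 showed higher goblet cell genes together with the interferon-response genes and the TYMS block, and lower mesenchymal genes. The goblet cell products SPINK4, TFF3 and FCGBP were 30.2-fold, 26.3-fold and 20.3-fold higher in 5M21 than in 5F31 as labelled, and MUC2, the main mucin of the colon, 12.8-fold (log2 ratio 3.68 ± 0.08). SECTM1 was 23.4-fold higher, MX1, an interferon-induced antiviral protein, 23.4-fold and NNMT 21.2-fold. The binding proteins IGFBP2 and IGFBP7 were 53.8-fold and 27.7-fold lower and the potassium channel KCNQ1 16.9-fold. BAMBI was lower too, well above background in the channel labelled 5M21 on 1 of 2 arrays, and CALD1 was at least 16.1-fold lower, not well above background in 5M21. KRTAP19-1 and KRTAP6-3, which encode hair keratin-associated proteins, were 26.1-fold and 15.5-fold lower. All had limma adjusted p of 0.000494 or less. Of 27 goblet cell and mucin genes 15 rose and 5 fell (16 and 6 adjusted over the list alone, camera adjusted p = 0.00317). For each list named here for 5M21 on the arrays titled as xenograft the adjusted p was 0.227 with an estimated correlation. Interferon-response genes rose in 40 of 43 cases with none lower (42 and 0 adjusted over the list alone, camera adjusted p = 2.85e-21), IFI6 by 3.97 ± 0.08, and antigen presentation genes in 13 of 19 with none lower (14 adjusted over the list alone, camera adjusted p = 4.69e-07). Detoxification and xenobiotic enzymes rose in 21 of 44 cases and fell in 5 (22 and 6 adjusted over the list alone, camera adjusted p = 0.00563), among them the metal-binding protein MT2A (2.15 ± 0.15), whereas CYP2B6 fell by 2.45 ± 0.08. Mesenchymal genes fell in 16 of 24 cases and rose in 3 (18 and 3 adjusted over the list alone, camera adjusted p = 3.11e-05), including the fibrillar collagens COL3A1 (-1.95 ± 0.09) and COL1A2 (-1.57 ± 0.08). Markers of stroma and blood, which a tumour can take from its host, fell in 8 of 20 cases and rose in 3 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0107). Integrins, laminins and matrix receptors fell in 19 of 39 cases and rose in 4, as adjusted over the list alone (camera adjusted p = 0.000977); ITGA6, a laminin receptor subunit, fell by 1.28 ± 0.08. Hypoxia genes fell in 10 of 29 cases and rose in 4 (12 and 4 adjusted over the list alone, camera adjusted p = 0.0355), among them CA9 (-1.72 ± 0.15) and VEGFA (-1.37 ± 0.10). Cell cycle genes fell in 15 of 46 cases and rose in 3 (16 and 3 adjusted over the list alone, camera adjusted p = 0.00563), for example the replication helicase subunit MCM2 (-1.43 ± 0.09). In all, 4376 of 12054 genes passed, 2293 higher and 2083 lower as labelled, 878 of them by at least 2-fold. Without 5M21 replicate 1 or 2 the counts were 2715 and 2717, and median centring in place of loess gave 0 in each xenograft comparison (5640 at unadjusted p below 0.05 for 5M21 and 5373 for 5F7 in the limma fit as reported).

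In the channel labelled 5F7 on the same arrays, PLAC8 was 43.9-fold higher than in that labelled 5F31, MX1 24.6-fold, SECTM1 18.2-fold, the leucine zipper transcription factor BATF 15.9-fold and FAM3D 15.9-fold. CXCR4 was 59.5-fold lower, BAMBI 29.1-fold, SPP1 23.8-fold, SYT13 22.8-fold, KCNQ1 20.5-fold, IGFBP2 20.5-fold and the ubiquitin-like protein UBD 18.5-fold, all with limma adjusted p of 0.000620 or less. Goblet cell and mucin genes rose in 16 of 27 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.000162), with the mucus lectin ZG16 10.3-fold, SPINK4 8.90-fold and MUC2 8.75-fold higher. The adjusted p of the lists named here for 5F7 was 0.231 to 0.325 with an estimated correlation. Interferon-response genes rose in 40 of 43 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 7.33e-21), and antigen presentation genes rose in 11 of 19 and fell in 2 (11 and 3 adjusted over the list alone, camera adjusted p = 0.000906). Mesenchymal genes fell in 16 of 24 cases and rose in 4 (17 and 4 adjusted over the list alone, camera adjusted p = 0.000103), with TGFBI (-2.17 ± 0.10) lower and AXL (1.51 ± 0.09) higher. Stromal and blood markers fell in 12 of 20 cases and rose in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 0.00166); the proteoglycan LUM was among those that rose (2.17 ± 0.10). Integrins, laminins and matrix receptors fell in 18 of 39 cases and rose in 3 (21 and 3 adjusted over the list alone, camera adjusted p = 0.000320), for example ITGB7 (-2.02 ± 0.11) and LAMB1 (-1.43 ± 0.17). Growth factors, cytokines and chemokines fell in 21 of 56 cases and rose in 8 (21 and 10 adjusted over the list alone, camera adjusted p = 0.0113), among them CXCL1 (-2.02 ± 0.08), while IGF2 was 5.61-fold higher. Wnt target and stem cell genes fell in 10 of 22 cases and rose in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.0113), with ASCL2 at -3.18 ± 0.13, EPHB3 at -2.95 ± 0.13 and the Wnt antagonist DKK1 higher by 2.47 ± 0.17. Cell cycle genes rose in 15 of 46 cases and fell in 6 (18 and 7 adjusted over the list alone, camera adjusted p = 0.0429), and detoxification enzymes rose in 19 of 44 and fell in 5 (19 and 6 adjusted over the list alone, camera adjusted p = 0.0113), with the metallothioneins MT2A, MT1G and MT1E 7.87-fold, 6.47-fold and 5.09-fold higher. In all, 4004 genes passed, 2085 higher and 1919 lower as labelled, 738 of them by at least 2-fold. Without 5F7 replicate 1 the count was 2384.

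Both clones moved in the same direction in 2494 genes on the human arrays titled as xenograft (1297 higher, 1197 lower), where independent lists would share 397 and 332, and 132 genes passed in opposite directions. Their ratios correlated across genes with r = 0.729 and a covariance of 0.249, against r = 0.479 and 0.172 for simulated unrelated clones with a shared reference and r = -0.00429 for unchanged ones; here too part of the excess may come from the shared RNA. The contrast of 5M21 with 5F7 passed in 734 genes, 394 with a higher and 340 with a lower ratio on the 5M21 arrays as labelled, 298 of them by at least 2-fold. It passed in 289 genes with the deposited log ratios and in 424 or 457 without 5M21 replicate 1 or replicate 2.

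TYMS encodes thymidylate synthase, which is inhibited by a metabolite of 5-fluorouracil. TYMS on chromosome 18 was higher than in 5F31 as labelled in every comparison on the human arrays: 7.74-fold in 5M21 and 3.56-fold in 5F7 on the arrays titled as culture, and 5.80-fold and 4.58-fold on those titled as xenograft, with limma adjusted p of 0.00970 or less. Its neighbours moved with it. Of the 12 tested genes in the list of TYMS and its neighbours at 18p11, 11 rose in 5M21 and 9 in 5F7 on the arrays titled as culture, and 12 and 10 on those titled as xenograft, with none lower (12, 9, 12 and 11 adjusted over the list alone). The camera adjusted p was 1.69e-07, 0.00160, 7.89e-08 and 6.89e-07, and with an estimated correlation 0.341, 0.473, 0.227 and 0.231 as adjusted p. USP14, a deubiquitinating enzyme of the proteasome, was 9.35-fold, 5.08-fold, 9.72-fold and 7.28-fold higher in the same order. The list of folate and fluoropyrimidine enzymes and transporters had as many members higher as lower in 5M21 on the arrays titled as culture, 10 of 37 each (12 and 10 adjusted over the list alone, camera adjusted p = 0.925). DPYD, which degrades 5-fluorouracil, rose there, well above background in the channel labelled 5F31 on 1 of 2 arrays, and the drug efflux pumps ABCC2 and ABCC5 fell by 1.97 ± 0.31 and 1.71 ± 0.12. On the arrays titled as xenograft the folate receptor FOLR1 fell by 1.72 ± 0.13 in 5M21 and by 2.48 ± 0.13 in 5F7.

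**Figure D2:**
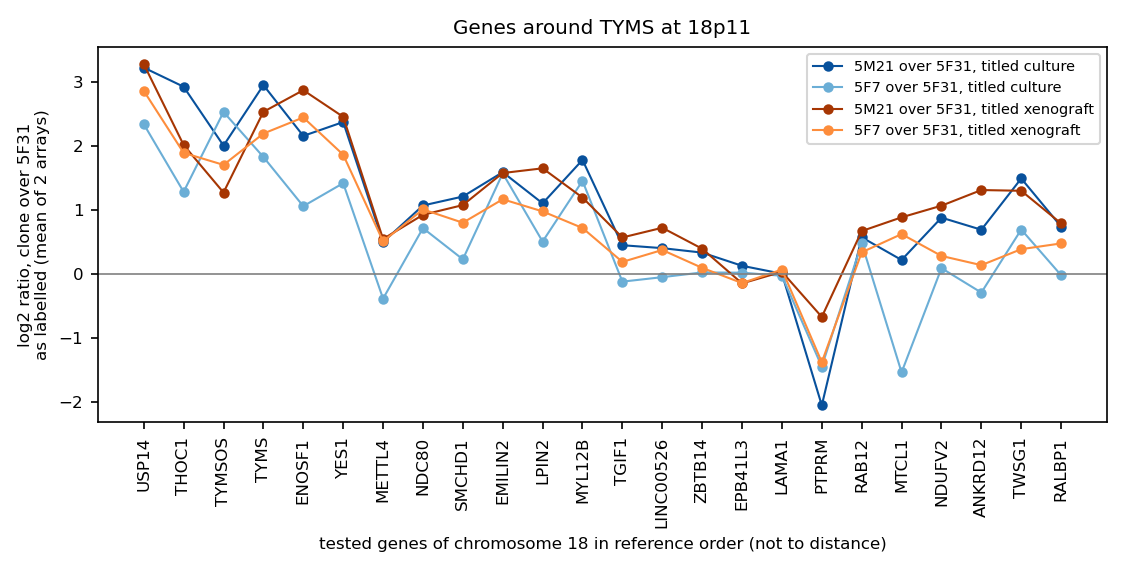
Log2 ratio of clone over 5F31 as labelled (vertical axis, mean of 2 arrays) of the first tested genes of chromosome 18 in reference order (horizontal axis, not to distance), with 1 line per comparison on the human arrays. USP14, TYMS and YES1 lie above 1 on all 4 lines, TYMS between 1.83 and 2.95.

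The clone effects themselves were compared between the human arrays titled as xenograft and those titled as culture in 1 model over all 8 arrays. Goblet cell genes differed most as a group, with directions as labelled. The effect of 5M21 over 5F31 was higher on the arrays titled as xenograft for 18 of 27 goblet cell genes and lower for none (median difference 1.57, camera adjusted p = 1.09e-11), and that of 5F7 for 21 of 27 and none (1.28, camera adjusted p = 1.71e-12). FCGBP went from -2.10 to 4.35 in 5M21 and from -2.37 to 1.55 in 5F7. Mesenchymal genes went the other way, with 13 of 24 lower in each clone and 1 and 0 higher (median differences -0.80 and -0.85, camera adjusted p = 1.77e-10 and 6.81e-08); TGFBI went from 3.40 to -1.04 in 5M21 and from 3.02 to -2.17 in 5F7. With an estimated correlation these 4 values were 0.0761, 0.0706, 0.0761 and 0.123 as adjusted p. The model takes genes tested in either set. On the arrays titled as culture, 22 of the goblet cell genes and 15 of the mesenchymal genes passed the filter on dim probes. For the others the ratio there rests on dim probes, so their difference mostly carries the ratio of the arrays titled as xenograft. WNT11 went from 4.38 to -2.21 in 5M21. The difference of effects passed in 2189 of 12337 genes for 5M21 (1364 higher, 825 lower) and in 2586 for 5F7 (1396 higher, 1190 lower). Of 11145 genes tested in both sets, 1039 rose and 1129 fell in 5M21 in both, where independent lists would share 393 and 405, and 216 passed in opposite directions; for 5F7 the numbers were 974, 930, 392, 346 and 188. The log2 ratios correlated between the sets with r = 0.598 for 5M21 and 0.568 for 5F7 across genes. The sets differ in array design, slides and scanner software as well as in their titles, so none of these can be told apart, and without xenograft 5M21 replicate 1 or 5F7 replicate 1 the counts were 595 and 777. Median centring in place of loess gave 0 for both clones, and scaling between arrays on all spots 569 for 5M21 and 1030 for 5F7.

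**Figure D3:**
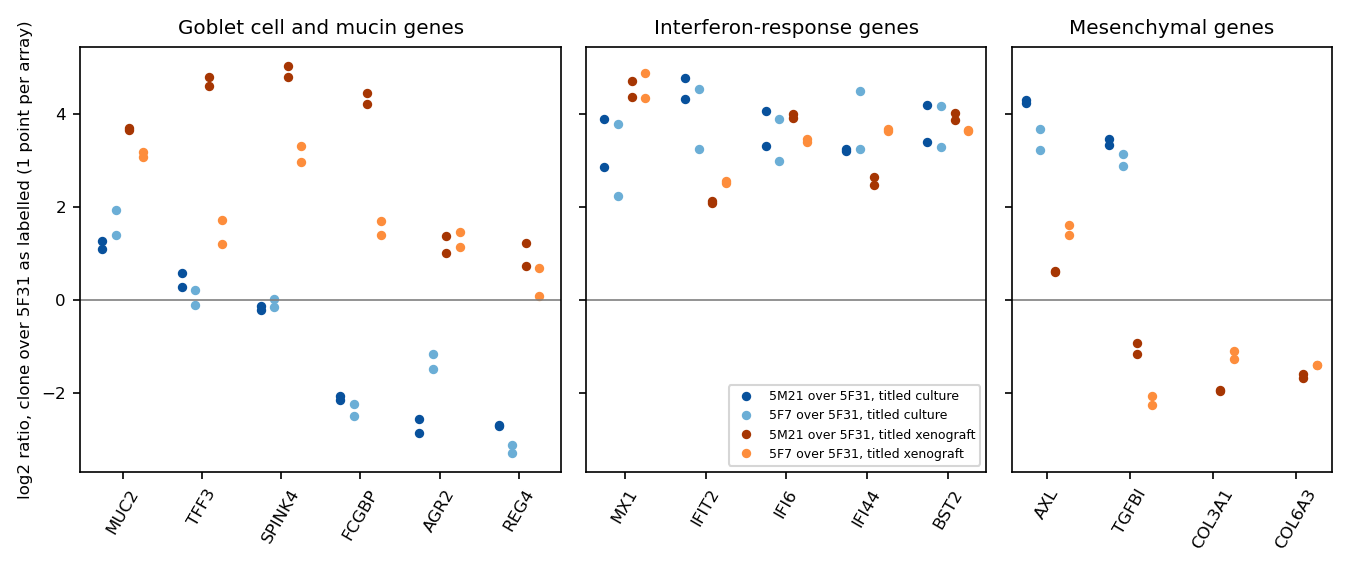
Log2 ratio of clone over 5F31 as labelled (vertical axis) of goblet cell, interferon-response and mesenchymal genes (horizontal axis), with 1 point per array and 1 colour per clone and set of human arrays. FCGBP lies at -2.10 (mean of 2 arrays) for 5M21 on the arrays titled as culture and at 4.35 on those titled as xenograft, while IFI6 lies above 3 in 5M21 on both (3.70 and 3.97); COL3A1 and COL6A3 were tested on the arrays titled as xenograft only.

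On the mouse arrays, which read host transcripts of the same kind of tumour, the deposited probes could not be paired with gene names, so results are given by probe, with directions as labelled. In 5M21 tumours 3155 of 19319 probes passed against 5F31 tumours, 1834 higher and 1321 lower, and 553 differed at least 2-fold. Probe A_52_P419059 was 21.4-fold higher and A_51_P369803 15.1-fold, whereas A_51_P495269 was 22.6-fold lower. A_51_P204350 was lower too, well above background in the channel labelled 5M21 on 1 of 2 arrays. In 5F7 tumours 2423 probes passed, 1683 higher and 740 lower, and 380 differed at least 2-fold. A_51_P432820 was 11.6-fold and A_51_P369803 7.97-fold higher, while A_51_P255699 was 5.94-fold and A_51_P402943 5.59-fold lower. All of these had limma adjusted p of 0.00211 or less. Both clones' tumours moved together in 1580 probes (1214 higher, 366 lower), where independent lists would share 160 and 50.6, with 80 in opposite directions. The count of 1580 was 249 or 173 without 5F7 replicate 1 or replicate 2, and 58.2% of the shared calls were higher with a dye coefficient per probe, against 76.8% as reported. Their ratios correlated with r = 0.640 and a covariance of 0.0905, against r = 0.458 and 0.0722 for simulated unrelated clones with a shared reference and r = -0.000195 for unchanged ones, so part of the excess may come from the shared RNA. The contrast of 5M21 with 5F7 tumours passed in 334 probes, 74 with a higher and 260 with a lower ratio on the 5M21 arrays, and 255 of them differed at least 2-fold. With a dye coefficient per probe 48.3% of the calls of this contrast had the higher ratio, against 22.2% as reported. It passed in 144 or 133 without 5F7 replicate 1 or replicate 2, and median centring in place of loess gave 0 for each count on the mouse arrays. The count for 5M21 was 1205 or 1381 without 5M21 replicate 1 or 2, and that for 5F7 301 or 203 without 5F7 replicate 1 or 2; with a dye coefficient per probe 52.4% of the 5F7 calls were higher, against 69.5% as reported. Human transcripts in these tumours may also bind mouse probes, which was not tested here.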

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

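The test of exchanged titles was chosen beforehand; those of host RNA, of a difference already there in culture, of overlapping probes and of copy number were chosen after the results were seen, and host RNA and copy number were reworded after their values were seen.

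Directions are as labelled and are not settled, because the channels labelled 5M21 and 5F7 agreed between arrays more closely than those labelled 5F31.

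The effects of the clones over 5F31 differed between the human arrays titled as xenograft and those titled as culture, as tested by the difference of effects in 1 limma fit. That fit takes genes tested in either set, so for some genes the ratio in 1 set rests on dim probes. In 5M21 the median difference (xenograft minus culture) was 1.57 for goblet cell and mucin genes, 0.93 for enterocyte genes, 0.67 for cholesterol and fatty acid synthesis genes, 0.58 for antigen presentation genes and 0.42 for detoxification enzymes. It was -0.80 for mesenchymal genes, -0.33 for stromal and blood genes, -0.26 for growth factors, cytokines and chemokines, -0.20 for proteases and -0.17 for cell cycle genes. In 5F7 it was 1.28 for goblet cell and mucin genes, 0.58 for cholesterol and fatty acid synthesis genes, 0.49 for enterocyte genes and 0.46 for TYMS neighbours, and -0.85 for mesenchymal genes, -0.58 for stromal and blood genes, -0.23 for proteases and -0.20 for growth factors, cytokines and chemokines. These lists passed camera with the preset correlation; none did with an estimated correlation (lowest adjusted p = 0.0761 in 5M21 and 0.0706 in 5F7).

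Single genes differed by more. In 5M21 the difference in log2 ratio was 6.45 for FCGBP, 5.67 for the matrix protein FMOD, 5.08 for SPINK4 and 4.72 for the oxidase NOX1, and -6.59 for WNT11, -4.67 for PHLDB2, -4.64 for KRTAP19-1 and -4.43 for TGFBI. In 5F7 it was 4.86 for the adhesion molecule CEACAM6, 3.91 for FCGBP, 3.58 for REG4 and 3.57 for the protease CAPN9, and -5.19 for TGFBI, -4.18 for WNT11, -4.06 for UBD and -3.86 for NEUROG3. Probes with no gene name passed in 1820 cases for 5M21 and 1901 for 5F7 on the arrays titled as culture, and in 1998 and 1706 cases on those titled as xenograft; no control sample sets a level for them.

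The array designs of the human arrays go against the series text, so the titles of culture and xenograft might be exchanged. Xenograft tissue brings stroma and blood, and an exchange needs the list of stromal and blood genes to be dimmer on the arrays titled as xenograft. The median of the per-gene differences in signal percentile was 6.60 points, higher there and beyond 99.94% of random lists matched on signal. The median percentile of the list was 26.8 there and 22.0 on the arrays titled as culture. Other lists rose by more on the arrays titled as xenograft: goblet cell and mucin genes by 13.02 points, interferon-response genes by 9.603 and hypoxia genes by 8.795. Some lists were dimmer there, such as cell cycle genes (-6.901). The rise is therefore not particular to stromal and blood genes, and it does not settle the titles. Array design and scanner software differ between the sets and stay open as a source of such differences, and 8 of the 36 genes of the list are also among the mesenchymal genes.

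On the arrays titled as xenograft, 16 of 24 mesenchymal genes fell as labelled and 3 rose in 5M21, and 16 fell and 4 rose in 5F7. Of 20 stromal and blood genes 8 fell and 3 rose in 5M21, and 12 fell and 3 rose in 5F7. With an estimated correlation the adjusted p was 0.227 for both lists in 5M21 and 0.276 and 0.231 in 5F7. A difference already there in culture needs a median below 0 on the arrays titled as culture, where the smaller median of the clones was 0.194, though that of 5M21 was -0.000935 with no filter on dim probes. The value of 0.194 covers the 15 mesenchymal genes tested there, against 24 on the arrays titled as xenograft. It cannot tell whether the genes tested only on the arrays titled as xenograft already differed in culture. Mouse host RNA bound by human probes may add to these genes. Over the mesenchymal genes, the median of the per-gene differences in signal percentile was 7.05 points, higher on the arrays titled as xenograft. The median percentile of the list was 56.9 there, with channels between 49.5 and 61.0. On the arrays titled as culture it was 28.4, with channels between 26.7 and 32.9. For hair keratin-associated genes the median of the per-gene differences was 4.29 points, higher there too and beyond 99.7% of random lists. By the median of the per-gene differences, goblet cell, interferon-response and hypoxia genes rose there by more than either list. By the median percentile of the list they rose less than the mesenchymal genes, from 55.2 to 67.5, 54.2 to 67.7 and 65.4 to 74.9. Antigen presentation genes rose from 49.2 to 78.0 by that measure, as much as the mesenchymal genes. Another list rose at least as much by either measure, so these rises cannot be assigned to host RNA. A change in the tumour cells in vivo would give such values too, and array design is confounded with the titles, so both remain open.

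TYMS rose, as labelled, in every comparison on the human arrays, and of the 12 tested genes in the list of TYMS and its neighbours at 18p11, 11 and 9 rose on the arrays titled as culture (5M21 and 5F7) and 12 and 10 on those titled as xenograft. With an estimated correlation the adjusted p was 0.341, 0.473, 0.227 and 0.231. Probes that bind the overlapping transcripts of TYMS and ENOSF1 cannot account for the other genes of the list, whose lowest median without that pair was 0.996. A copy number of the region that differs between 5F31 and both other clones is a candidate explanation that cannot be told apart from regulation of the genes, since DNA was not measured. The next 12 tested genes of chromosome 18 lay at the 95.3, 50.8, 99.0 and 89.6 percentiles of random runs (culture 5M21 and 5F7, xenograft 5M21 and 5F7; lowest 50.77), and where a difference would end was not tested.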

How the results depend on the processing

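Ignoring the outlier marks of xenograft 5F7 replicate 2 and scaling set by the tested genes alone were chosen after seeing the data. Counts are of genes or probes past the limma threshold and, unless a reason is given, the cause was not tested.

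Without background subtraction the contrast of 5M21 with 5F7 on the arrays titled as culture passed in 591 genes (2 as reported) and the difference between the human sets in 4022 for 5F7. The deposited log ratios, from the scanner files and from the series tables alike, gave 346, 289 and 176 for 5M21 against 5F7 on the arrays titled as culture, as xenograft (human) and on the mouse arrays. Median centring in place of loess gave 263 for 5M21, 312 for 5F7, 1 for 5M21 against 5F7 and 149 for both clones on the arrays titled as culture, and 0 for each count of the human arrays titled as xenograft, the mouse arrays and the difference between the human sets; it moved the median of all mouse probes to -0.19 and -0.30 and that of 5F7 on the arrays titled as culture to -0.12. Scaling between arrays on all spots gave 0 for each count on the arrays titled as culture, where it widened the spread of 5F7 replicate 2 from 0.534 to 1.02, and 569 and 1030 for the differences between the human sets in 5M21 and 5F7; scaling set by the tested genes alone gave 216 for 5M21 against 5F7 on the arrays titled as culture. Counts at unadjusted p below 0.05 as reported lay between 2136 and 5990 by limma.

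No filter on dim probes gave 524 probes for 5M21 against 5F7 on the mouse arrays and turned the mesenchymal median of 5M21 on the arrays titled as culture to -0.000935. Requiring both channels well above background on every array gave 1 and 204 for 5M21 against 5F7 on the arrays titled as culture and the mouse arrays, with fewer genes tested. A dye coefficient per gene gave, for 5M21, 5F7, 5M21 against 5F7 and both clones, 7087, 7304, 2433 and 4835 on the arrays titled as culture, 8393, 8272, 5764 and 5525 on those titled as xenograft, and 10155, 9923, 4151 and 6480 on the mouse arrays, and 6145 and 6391 for the differences between the human sets. A 2-fold minimum, which only removes genes, gave 1425, 1492 and 786 (5M21, 5F7, both) on the arrays titled as culture, 878, 738, 298 and 449 (with 5M21 against 5F7 before both) on those titled as xenograft, 553, 380 and 199 on the mouse arrays, and 856 and 924 for the differences. Of 76 list tests 42 passed camera, 0 with an estimated correlation and 75 by fry in either direction, which asks another question. By fry in 1 direction, 13 (5M21) and 12 (5F7) of 19 lists passed on the arrays titled as culture. On those titled as xenograft 18 and 14 did. Fry does not set a list against the other genes. Ignoring the outlier marks gave 4406, 4029, 656 and 2465 of 12748 genes.

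Leaving out 1 array, where the lone array is assumed to vary like the others, gave 329 to 4177 genes for 5M21, 1367 to 3331 for 5F7, 0 to 0 for their contrast and 272 to 2185 for both on the arrays titled as culture. The ranges were 2715 to 4734, 2384 to 3951, 424 to 629 and 1688 to 1981 on the human arrays titled as xenograft, 1205 to 2309, 203 to 2321, 133 to 207 and 173 to 894 on the mouse arrays, and 595 to 2406 and 777 to 2475 for the differences. The lowest came without a 5M21 or 5F7 array of the comparison itself, with fewer arrays. Such a fit leaves that comparison 1 array in 1 dye orientation. A dye effect then no longer cancels and cannot be told apart from the clone effect, which holds for the counts above as well.

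Of 359 named gene values, 358 kept direction and side of the threshold without background subtraction and 359 with the deposited log ratios of the scanner files, against 99 with median centring and 187 with scaling between arrays. Signal over background limits the dim probes: 46.6% to 91.6% of red spots were well above background. Replicate numbers follow only the order of the records and run with the dye orientation in each experiment, so the replicate number as a block is the fit with a dye coefficient, which gave 2433, 5764 and 4151 for 5M21 against 5F7.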

Other observations

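The tests of exchanged channel labels and of neighbouring genes, and the genes named for the contrast of 5M21 with 5F7, were chosen after the values were seen.

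The channels labelled 5M21 and 5F7 agreed more closely than the channels labelled 5F31, although 5F31 is the RNA that the labels put on every array. The SD between the 5M21 and 5F7 arrays was larger in the channel labelled 5F31 by a factor of 3.38 (culture), 3.53 (xenograft, human) and 3.25 (mouse), and by at least 1.89, 2.11 and 2.66 in either dye orientation. In the processed signals as deposited the factors were 3.43, 2.63 and 2.43. These values are those that channel labels exchanged on every array would give (lowest of the 3 experiments after loess, both dye orientations together, 3.25), and all directions in the report would then turn. The same RNA in the channels of both clones, with separate 5F31 preparations, could give them too and was not tested. Labels that are right, with 1 5F31 RNA and clones that differ, need a factor below 1. The deposited log ratios run the same way as the labels and settle nothing. With the labels exchanged, the filter on dim probes would keep 25772, 24085 and 20459 probes in place of 24927, 23402 and 19319.

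On the human arrays titled as xenograft, the ratio over 5F31, as labelled, was higher on the 5M21 than on the 5F7 arrays for PIGR, the epithelial receptor that carries IgA (log2 difference 6.69 ± 0.15), the elastase inhibitor PI3 (3.71 ± 0.12), UBD (3.25 ± 0.19) and TFF3 (3.25 ± 0.20), among others. It was lower for KRTAP19-1 (-4.65 ± 0.17), KRTAP6-3 (-4.04 ± 0.16), the globin genes HBQ1 (-3.82 ± 0.14) and HBD (-3.54 ± 0.16) and the DNA repair gene MGMT (-3.51 ± 0.15), with limma adjusted p of 0.00683 or less for all of these. The differences lay in the channels labelled 5F31. PIGR had log2 signals of 9.87 and 10.36 in the channels labelled 5M21 and 5F7, and of 6.67 and 13.84 in the channels labelled 5F31 on the same arrays. PI3 had 11.96 and 11.97 against 8.91 and 12.63, KRTAP19-1 6.55 and 6.36 against 11.26 and 6.41, and MGMT 10.51 and 10.53 against 10.52 and 7.02. Of 16 tested hair keratin-associated genes 6 fell and 2 rose in 5M21, and 2 fell and 0 rose in 5F7 in the limma fit, as labelled.

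Among lists not described above, extracellular proteases and inhibitors had 21 of 43 members higher and 11 lower in 5M21 on the arrays titled as culture (camera adjusted p = 0.0242, and 0.341 as adjusted p with an estimated correlation), and growth factors, cytokines and chemokines 18 of 47 higher and 7 lower (camera adjusted p = 0.0242, and 0.341 likewise). Stromal and blood genes had 4 of 9 higher and none lower there (camera adjusted p = 0.0404, and 0.428 likewise). In 5F7 on the same arrays none of these lists passed (camera adjusted p = 0.0910, 0.912 and 0.485 in the same order). Enteroendocrine genes had 3 of 5 members higher and 1 lower in 5M21 (camera adjusted p = 0.223), and epithelial junction and keratin genes 6 of 40 higher and 10 lower (camera adjusted p = 0.925). In all, 42 of 76 list tests passed camera and 0 with an estimated correlation; in 9 of the 76, none of them a call, the median, the mean and the test differed in sign.

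Genes from RIOX2 onwards on chromosome 3 were mostly lower than in 5F31 as labelled. Over 349 genes the median log2 ratio was -0.78 and -0.61 for 5M21 and 5F7 on the arrays titled as culture and -0.65 and -0.50 on those titled as xenograft, with 80.5% to 84.5% of the genes below 0. Over the 325 genes before it the medians were 0.06, -0.07, -0.05 and -0.04. The starting gene was chosen after the values were seen.

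Regional gains or losses between the clones may underlie runs of neighbouring genes that move together. Of windows of 15 genes, 27 regions outside chromosome 18 lay beyond all 20 shuffled orders at the same place in both human sets, 17 of all 29 regions being those of 5M21 and 12 those of 5F7. On chromosome 3 lay 13 regions of 5M21 and 8 of 5F7, all lower than in 5F31 as labelled. Some of these regions overlap, so their numbers are not counts of separate regions. Co-regulated neighbours would give such regions too, the comparisons share 1 RNA on all arrays, and DNA was not measured, so this is a hypothesis.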
